A study of Mus musculus with 4 samples.

How the data were processed

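Genomic DNA of mouse haploid neural stem cell-like cells was measured in 4 samples. These are cells with a single chromosome set, derived from haploid embryonic stem cells of a 129Sv background through embryoid bodies and a medium with growth factors FGF2 and EGF, inhibitors of BMP and activin/TGF-beta receptors and a ROCK inhibitor. Per the labels' protocols, the cells were transfected with a piggyBac gene trap plasmid and a transposase, and cells carrying a trapped gene were selected with G418. The junctions between transposon and genome were amplified by splinkerette PCR, a nested PCR on DNA ligated to a partly unpaired adapter, and sequenced on a HiSeq 2500.

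The 4 samples fall into 2 libraries of 2 samples by the processed table that each sample's label names. The labels give no treatment that differs between the libraries, and they do not explain the last number in the sample titles. Each table pools its 2 samples with no column per sample, so no value per library has a replicate check. A test between the libraries compares these 2 pools of reads and not conditions, and genes are not replicates.

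Each deposited table lists, per the file headers, a gene symbol, its RefSeq transcripts, and the count of nonredundant reads and of redundant reads in that gene. Both columns are raw whole-number counts by the authors with no normalization, per the values, and a gene appears in a table only if it has at least 1 read. The submitters' processing notes name CASAVA, BWA and the mouse build mm9, with no versions. How a read was assigned to a gene, which reads were filtered and how nonredundant was defined are not given in the sources used here. No gene had more nonredundant than redundant reads. Nonredundant reads were used for every main value, since they carry fewer PCR copies. They are still not counts of independent insertions, because PCR reads without molecular identifiers are not independent molecules, and all intervals cover counting error only.

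The tables give no position, strand, annotation category or distance. Distinct sites, category shares, the genic share against random positions, positions in both libraries, orientation, distance to transcription start sites and genes with several sites were therefore not analysed here, although tests of them had been fixed beforehand. The rule for named genes was applied with nonredundant reads in place of distinct sites. It names up to 30 genes listed in both libraries by their summed reads, the 10 genes with most reads per library, and up to 5 members of each gene list by summed reads. Genes with 100 or more reads in both libraries were named after their values were seen.

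Gene symbols were matched through the transcripts, then by symbol or synonym, to a RefSeq gene table of assembly GRCm38.p6. This differs from the authors' build, so none of its coordinates are printed. Its gene lengths served only to order and match genes, and its chromosomes only to group them. Of the listed genes, 4174 of 4184 matched in library 1 and 3163 of 3168 in library 2, and 4168 and 3158 of these were among the 21035 genes with curated transcripts that formed the background.

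Intervals of shares were exact Clopper-Pearson 95% intervals. The overlap of the gene lists was tested with a one-sided exact hypergeometric test. Because gene length differs so much among listed genes, the overlap was also set against 10000 draws of genes matched on length, from the nearest 200 genes by length rank. Read support was compared with Fisher's exact tests and a permutation test of the median (100000 resamples), which is uninformative here because most genes have 1 read. Chromosome counts were compared with a chi-square permutation test (100000 resamples), and Benjamini-Hochberg adjustment was used within each family. The tests of read support and of chromosomes treat the 2 gene lists as independent, although many genes are in both. The 13 gene lists were fixed before the data were examined. For each list, the number of members with at least 1 read was compared with 10000 random lists of the same size, each member replaced by one of the nearest 200 genes by length, in a two-sided permutation test whose smallest p is 0.0002. Other members of the same list could be drawn as replacements. The p-values were adjusted over the 13 lists alone, separately for either library, library 1 and library 2. All members of the lists could be matched, and symbols of the same gene, such as Hprt and Hprt1, were counted as 1 gene. Some genes that the naming rule gives are not reported here by name; they remain in the counts.

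In all, the list test was run in 8 settings, which makes 312 list tests, and the difference between libraries was tested for 13 lists at 2 read minima, which makes 26 tests. The alternatives fixed before the data were examined were a minimum of 2 or 10 nonredundant reads, chromosomes 1 to 19 and X only, protein coding genes only, the nearest 50 genes, and Fisher's exact test without length matching. Alternatives added after seeing the data were the length-matched overlap with its variants, a minimum of 2 redundant reads, 10 reads together with the nearest 50 genes, and the tests of the difference between libraries at both read minima. Each part of the closing section says which of its tests were chosen after the results were seen.

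On simulated data over 21035 genes (60 simulations each), the list test called 3.33% of neural stem cell lists, 5% of core essential lists and 5% of chromatin lists in library 1 without an effect. With the odds of being listed raised 3-fold it called 70%, 100% and 100%. The length-matched overlap test called 1.67% of simulations of libraries independent given length and 100% of those with 300 added shared genes. Neither the long synaptic and adhesion list nor a minimum of 10 reads was simulated, so these rates do not cover them. The simulated listings followed length through a window of neighbours like that of the tests, so low rates without an effect were built in. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.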

Results

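Transposon insertions were mapped in pools of haploid neural stem cell-like cells, made as mutant libraries for genetic screening. In a haploid cell, an insertion that disrupts a gene leaves no second copy, so a library is described by the genes it has hit. The data are 2 tables of reads per gene, one for each library of 2 pooled samples. Library 1 listed 4184 genes with 55442 nonredundant and 877870 redundant reads. Library 2 listed 3168 genes with 48750 nonredundant and 1300140 redundant reads. Over the library totals there were 15.8 redundant reads per nonredundant read in library 1 and 26.7 in library 2. This does not hold for most genes, since the 2 counts were equal in 2358 genes of library 1 and 1780 of library 2. Together the libraries listed 5614 genes, and 1738 of these were in both. There are no replicates per library. Reads are PCR products, so their number does not count independent insertions or cells.

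In library 1, the gene with most nonredundant reads was Ralgapa1, which encodes a subunit of a GTPase-activating complex for Ral proteins, with 1506 reads or 2.72% of the library (95% interval 2.58 to 2.86, counting error only). It was followed by Map7, a microtubule-associated protein, with 1315 reads, by Myo6, an unconventional myosin, with 1017, and by D6Wsu163e with 949. The next places were held by Clnk (837 reads), Dok6 (693), Iffo2 (679), the delta opioid receptor gene Oprd1 (674), the Eph receptor gene Epha4 (668) and 1700113H08Rik (642). In library 2, Stx1a, a syntaxin of the synaptic vesicle fusion machinery, had 4988 reads or 10.2% of the library (95% interval 9.96 to 10.5). Slc8b1, a mitochondrial sodium-calcium exchanger, had 4497 reads, the neurexin gene Nrxn3 had 2878, Ski, a repressor of SMAD-dependent transcription, had 2469, and Cpeb1, a regulator of mRNA polyadenylation, had 1803. Dscr3 (994 reads), Zyg11b (941), Armc7 (797), the Eph receptor gene Ephb1 (675) and the integrin gene Itgb3 (573) completed the 10 genes with most reads.

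The leading genes held a larger part of library 2. Its 10 genes with most nonredundant reads took 42.3% of these, and its 10 genes with most redundant reads took 80.2% of those, against 16.2% and 41.2% in library 1. The Gini coefficient of nonredundant reads over listed genes was 0.857 in library 1 and 0.898 in library 2. The median gene had 1 read in both libraries, a value set by the many genes with a single read, so a test of the median could show no difference. Genes with exactly 1 read made up 53.7% of library 1 (95% interval 52.2 to 55.2) and 59.7% of library 2 (58.0 to 61.4). Genes with 10 or more reads numbered 499 (11.9%, 95% interval 11.0 to 12.9) in library 1 and 294 (9.28%, 8.29 to 10.3) in library 2. This share differed between the libraries by Fisher's exact test (adjusted p = 0.000613 over 4 tests of read support), as did the share with 2 or more reads, 46.3% against 40.3% (Fisher's exact test, adjusted p = 1.16e-06). The share with 100 or more reads was 3.01% (126 genes) and 2.46% (78 genes), a difference that did not pass Fisher's exact test (adjusted p = 0.231). Genes with 10 or more reads held 87.3% of library 1 reads and 89.6% of library 2 reads.

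Few genes had many reads in both libraries, with 43 at 10 or more reads in each. Stx1a had 11 reads in library 1, Slc8b1 8, Nrxn3 30, Ski 9 and Cpeb1 4. Conversely, Map7 had 3 reads in library 2, Myo6 16, and D6Wsu163e, Dok6, Epha4 and 1700113H08Rik 2 each, while Ralgapa1, Clnk, Iffo2 and Oprd1 were not listed there. Armc7 was not listed in library 1. Among the 30 shared genes with the highest summed reads (444 to 4999), 13 had over 90% of their reads in library 1 and 14 had over 90% in library 2. The first group includes Pawr (539 and 2 reads), Tmem71 (509 and 1), Card6 (492 and 1), Pstpip2 (486 and 4), Vps53 (467 and 1) and Acsl4 (457 and 1). The second includes Adamts2 (4 and 563), Fam178b (1 and 532), Arsb (4 and 497), Siah2 (1 and 468), Dock9 (2 and 460) and Pde4dip (6 and 438). Across the 1738 shared genes, Spearman's rho of reads was 0.273 and Pearson's r of log2 reads 0.150. These are correlations across genes, which are not independent replicates.

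Just 4 genes had 100 or more reads in both libraries. Among them were Ephb1 (370 and 675 reads), the cadherin gene Cdh13 (224 and 243) and Nckap5 (114 and 212). This small group was chosen after its values were seen. A length-matched permutation test expected 1.99 such genes (95% of draws 0 to 5), and the excess did not pass it (one-sided p = 0.136). At 10 or more reads, 43 genes were shared against 32.3 expected (23 to 42) in that permutation test (one-sided p = 0.0224). This count lies just above the range of draws, and no closer match on length was run at this minimum. Whether length accounts for the excess at 10 or more reads therefore stays open.

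**Figure D1:**
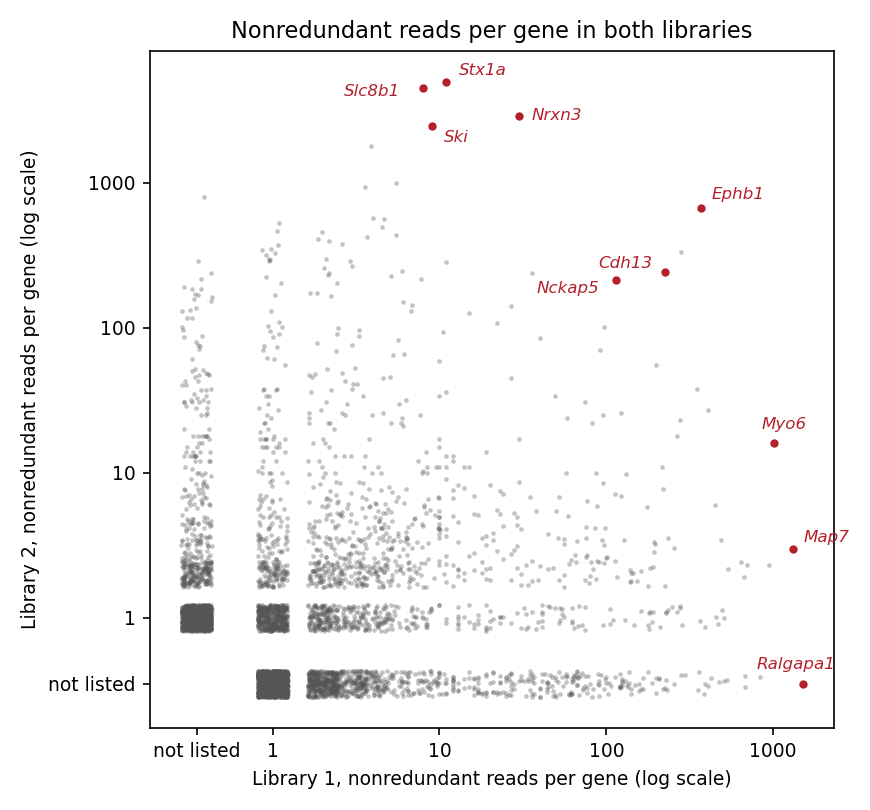
Nonredundant reads per gene in library 1 (x axis) and library 2 (y axis), both on log scales, with genes absent from a table drawn at "not listed". Each point is a gene, points under 10 reads are spread slightly at random except the named genes in red, and Stx1a (11 and 4988 reads) and Map7 (1315 and 3 reads) lie near opposite edges while Ephb1 (370 and 675 reads) lies high in both.

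Both libraries listed the same genes more often than chance. Of the 4168 and 3158 genes in the background of 21035, 1732 were in both libraries against 625.7 expected for random genes, a ratio of 2.77 (exact hypergeometric test, one-sided, log10 p = -514). Shared genes made up 41.5% of the genes listed in library 1 and 54.9% of those in library 2. Most of this excess went with gene length. Draws matched on length gave 1438 shared genes on average (95% of draws 1393 to 1484), which leaves a ratio of 1.20 (permutation test, one-sided, p = 0.0001, the smallest the draws can give). Both p-values treat genes as independent and describe these libraries.

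Long genes were listed far more often than short ones. Genes were split into 10 classes of equal size by length. In the shortest class, 0.333% were listed in each library (95% interval 0.134 to 0.684). The share rose with each class and reached 71.6% in library 1 (69.6 to 73.5) and 58.3% in library 2 (56.1 to 60.4) in the longest class. There, 48.2% of genes were in both libraries (46.1 to 50.4). The lengths are those of GRCm38.p6, not of the authors' build.

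**Figure D2:**
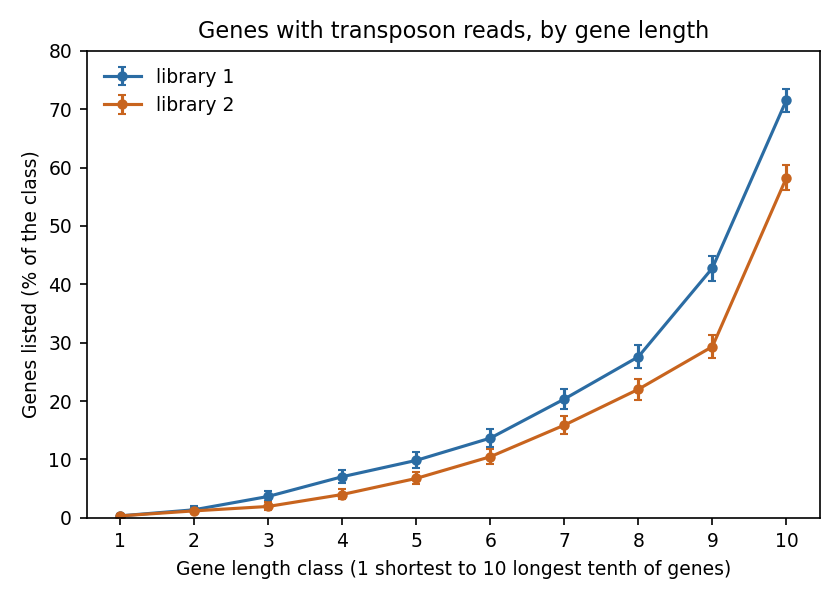
Percent of genes listed in each library (y axis) by class of gene length (x axis, 1 shortest to 10 longest, equal numbers of genes), with exact 95% intervals as bars. Both lines rise from 0.333% in the shortest class to 71.6% in library 1 and 58.3% in library 2.

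Gene lists fixed before the data were examined asked whether genes of neural stem cells, of the pathways acted on by the culture medium, or of essential functions were listed more or less often than genes of like length. None of the 13 lists passed an adjusted p of 0.05 in either library, in library 1 or in library 2 (permutation test against length-matched random lists; lowest adjusted p = 1, 0.84 and 0.263). Without adjustment, 0, 0 and 1 lists passed. Each number below counts members with at least 1 read, beside the mean of random lists. Most listed genes had exactly 1 read, which is weak evidence that a gene was hit, as the Y-linked genes of the closing section show. A count near that of random lists therefore need not describe insertions, nor show that insertions in a list were tolerated.

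Of 50 neural stem cell genes, 19 were listed in either library against 17.2 expected. The N-cadherin gene Cdh2 had 67 reads in library 1 and was not listed in library 2, as was Pax6, a transcription factor of neural progenitors, with 27. Zbtb16 had 1 and 38 reads in libraries 1 and 2, Dach1 3 and 30, and the RNA-binding Musashi gene Msi2 4 and 26. Genes of other neural types gave 13 of 30 members against 12.9 expected, with the splicing factor Rbfox1 at 145 and 2 reads, the neuronal microtubule protein Map2 at 41 and 1, and the glutamate transporter Slc1a2 at 1 and 7. Of 31 pluripotency genes 8 were listed against 8.03 expected, led by Jarid2, a partner of the Polycomb complex, with 28 and 3 reads, and Sall4 with 9 reads in library 2 alone. Genes of other germ layers were listed for 4 of 30 members against 7.21 expected. These were Gata4 with 3 reads, Gata6 and Ptprc with 2 each and Hnf4a with 1, all in library 1. Library 2 listed 0 of the 30 against 3.72 expected, the one list below 0.05 before adjustment (permutation p = 0.0202, adjusted p = 0.263).

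Members of the pathways acted on by the medium were also close to the random lists. For BMP, activin, TGF-beta and ROCK signalling, 15 of 33 were listed against 17.1 expected. Ski had 9 and 2469 reads, the BMP receptor gene Bmpr2 80 and 2, and Rock2 6 and 2. For FGF and EGF signalling, 18 of 40 were listed against 17.9 expected. The RAS regulator Nf1 had 182 reads in library 1 and 1 in library 2, Gab2 had 7 and 32, and Pik3r1 (44 reads) and Map2k1 (40) were in library 1 alone. Cell cycle, p53 and mitosis genes gave 15 of 42 against 12.4 expected, with the transcription factor E2f3 at 68 and 1 reads and the checkpoint kinase Atm at 4 and 2. Parkinson disease, mitophagy and manganese genes gave 13 of 35 against 11.8 expected. The autophagy receptor Optn had 106 reads in library 1 alone, and the mitophagy receptor Fundc1 had 10 reads in library 2 alone. Of 12 mismatch repair and purine salvage genes, 3 were listed against 3.97 expected. They were Msh3 with 3 and 1 reads, Pms1 with 1 in library 1 and Pms2 with 1 in library 2.

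Core essential complexes, of which ribosome, proteasome and spliceosome subunits are examples, had 41 of 228 members listed against 35.3 expected. At 2 or more reads 9 were listed against 11.8 expected, and at 10 or more reads 4 against 3.41. The leading member was Eif2ak4 with 31 reads in library 1, which the symbol pattern of the list includes but which encodes a stress-response kinase and not a subunit of the translation initiation factor. Snrpd1 had 18 reads and Rps4x 12 in library 1 alone, and Psmb5 had 1 and 14. Chromatin regulators had 67 of 153 members listed against 65.1 expected. Arid5b had 1 and 329 reads, the acetyltransferase gene Kat6a 256 and Brd8 220 in library 1 alone, and the demethylase gene Phf2 88 in library 2 alone. In library 2, whether or not also in library 1, 46 of the 153 were listed against 36.3 expected (permutation p = 0.0592, adjusted p = 0.385). Olfactory, vomeronasal and taste receptor genes had 54 of 1495 members listed against 47.8 expected, led by Vmn2r59 with 36 reads in library 1. At 2 or more reads 10 of them were listed against 12.6 expected, and at 10 or more reads 1 against 3.93. Long synaptic and adhesion genes had 39 of 40 members listed against 37.0 expected. Nrxn3 had 30 and 2878 reads, Auts2 445 and 6, the dystrophin gene Dmd 406 and 27, Macrod2 123 and 26, and Magi2 132 and 9.

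Without length matching, 6 lists passed Fisher's exact test in either library, long genes with a ratio of 3.67 and olfactory receptors with 0.136 among them. At 10 or more reads, the long synaptic and adhesion list passed, with 29 members at a ratio of 1.52 to the expectation (permutation test, adjusted p = 0.0364), but not with the nearest 50 genes as neighbours (ratio 1.28, permutation test, adjusted p = 0.322). Other list members were among the possible draws, so this loss cannot be put down to length alone.

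**Figure D3:**
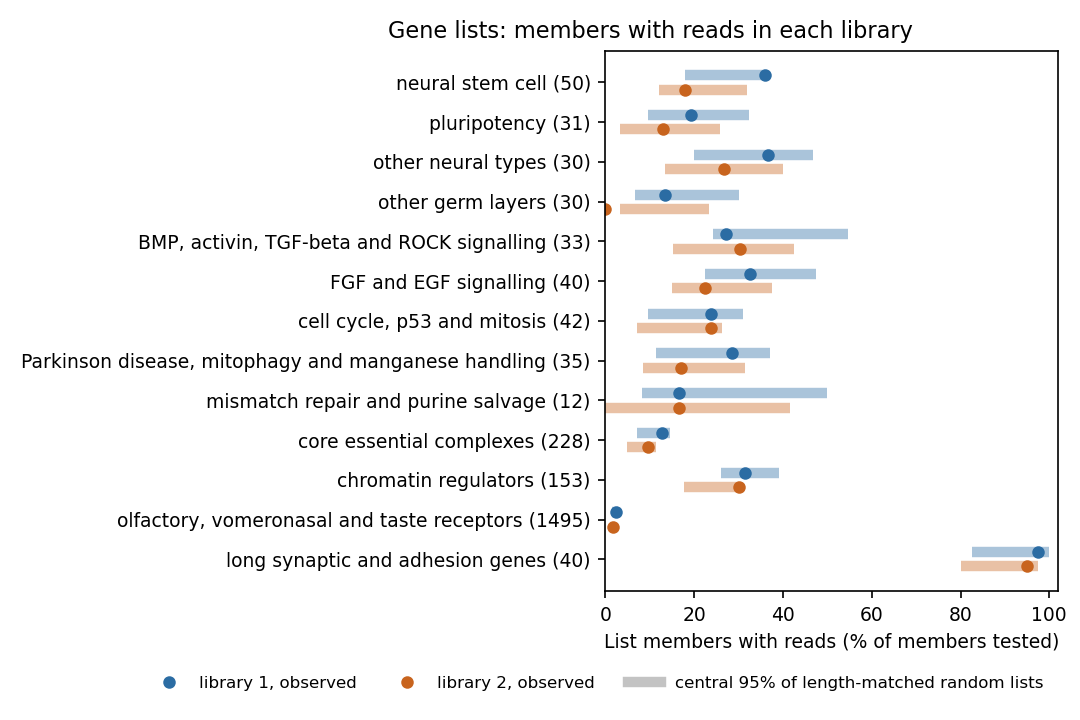
Percent of each list's tested members with at least 1 read (x axis) for the 13 lists (y axis, members tested in brackets), with points for library 1 and library 2 and bars for the central 95% of length-matched random lists. No list passed the adjusted threshold, and the library 2 point for other germ layers lies at 0 of 30 members against 3.72 expected.

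No difference between the libraries in the chromosomes of their listed genes was detectable (chi-square permutation test over 21 chromosomes, p = 0.985). The test treats the 2 gene lists as independent, although 1732 genes are in both. These genes count alike on both sides, which pulls p towards 1 and makes a difference harder to detect. Chromosome 2 held 7.61% of library 1 genes and 7.57% of library 2 genes, and chromosome 1 held 7.22% and 6.97%. The X chromosome held 150 genes (3.60%) in library 1 and 116 (3.67%) in library 2. No chromosome passed Fisher's exact test after adjustment (lowest adjusted p = 0.972), a test with the same limit.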

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

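The tests of the difference between libraries, all ways of matching this difference on length, the enrichment with 50 neighbours at 10 reads and the minimum of 2 redundant reads were chosen after the data were examined; the enrichment at 2 or 10 reads with 200 neighbours was fixed before. Long synaptic and adhesion genes reached 10 or more reads more often in library 1, in 28 of 40 members, than in library 2, in 8 of 40. Of the genes at 10 or more reads in a single library, 21 of 453 in library 1 alone were members of this list, against 1 of 251 in library 2 alone, a difference between libraries that passed Fisher's exact test (p = 0.00106, adjusted p = 0.0138 over 13 lists and 0.0277 over all 26 such tests). Auts2 (445 and 6 reads), Magi2 (132 and 9), Wwox (122 and 8), Cntn5 (98 and 5) and Pard3b (97 and 3) were among them. Nrxn3 (30 and 2878), by far the member with most reads, Ntm (10 and 59), Opcml (27 and 45) and Dpp6 (1 and 15) had more reads in library 2. The listed members summed to 1881 reads in library 1 and 3236 in library 2, and to 1851 and 358 without Nrxn3, so the lean of the summed reads turns on that 1 gene. At a minimum of 1 read, 39 and 38 of the 40 members were listed (Fisher's exact test, adjusted p = 1). Only 1 and 0 members were then in a single library, too few for that test to show a difference. At 2 or more reads the ratio to length-matched lists was 1.23 in library 2 (37 of 40 members, permutation test, adjusted p = 0.065). In library 1 it was 1.08 (38 of 40 members, permutation test, adjusted p = 0.971). With 35.2 of 40 members expected in library 1 and 30.1 in library 2, the ratio of library 1 had less room to rise. The 2 ratios therefore do not rank the libraries. At 2 or more redundant reads they were 1.20 in library 2 and 1.07 in library 1. The difference at these minima was not tested.

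Gene length may account for part of this, because library 1 had more genes at 10 or more reads and the members are among the longest genes. Length was matched in 6 ways (the nearest 5, 10, 20 or 50 genes by log length, and the nearest 50 or 200 by length rank). The difference of 20 members lay above the central 95% of draws each time, but the nearest 200 hardly match length. With them, 3 of 40 members have neighbours whose median length is within 10% of theirs, and the median neighbour has 0.569 of a member's length. That way and the 16.2 expected below with 200 neighbours therefore carry little weight. The closest upper bound of the draws was 18, with the nearest 5 genes, where 11.5 of the 20 were expected from length. There, 10 of the 40 members had neighbours whose median length was not within 10% of theirs. Among the 30 members whose neighbours had a median length within 10% of theirs, the difference was 16, against an upper bound of 13. The tests argue against length as the whole cause, but with limits. The 6 ways reuse the same neighbours, so they are not separate support. Neighbours were drawn for each member independently although long members can share them, which may make the bounds too narrow. The enrichment in library 1 itself depends on the match (28 members against 16.2 with 200 neighbours, permutation test, adjusted p = 0.0052, and against 20.9 with 50, permutation test, adjusted p = 0.199). The draws of these enrichment tests could take other list members, which raises what is expected. With list members left out, 15.96 to 18.65 were expected in library 1 with the nearest 5 to 50 genes by log length. The loss with 50 neighbours can therefore not be put down to length alone, and the enrichment with members left out was not tested. With 1 pool per library and nothing in the labels to tell the libraries apart, no biological explanation was tested.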

How the results depend on the processing

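The 2-redundant-read minimum, the 10-read minimum with the nearest 50 genes and the length-matched overlaps were chosen after seeing the data; the others were planned. Higher read minima reduced the genes tested, by construction. Library 1 kept 1927, 496 and 2445 genes at 2 or more nonredundant, 10 or more nonredundant and 2 or more redundant reads, library 2 kept 1275, 294 and 1765, and 661, 43 and 884 were shared. At minima up to 10 reads the overlap stayed above that of random genes, with ratios from 2.76 to 6.20. Against length-matched genes the ratios were 1.18 to 1.33. At 10 or more reads the 43 shared genes lay just above the range of length-matched draws (23 to 42). No closer match on length was run there, so that excess depends on a single match. At 100 or more reads the overlap did not pass with length matching (4 genes). Of the lists in either library, those that passed Fisher's exact test without length matching were BMP, activin, TGF-beta and ROCK signalling (ratio 1.71, below 1 when matched), FGF and EGF signalling (1.69), core essential complexes (0.676, above 1 when matched), chromatin regulators (1.65), olfactory, vomeronasal and taste receptors (0.136, above 1 when matched) and long synaptic and adhesion genes (3.67). In library 1, core essential complexes (0.642), chromatin regulators (1.58) and olfactory receptors (0.125) also turned direction, and the neural stem cell list passed (1.82, Fisher's exact test, adjusted p = 0.0182), as did long genes (4.92). The ratios differ because the expectation no longer follows length; the test differs too, so why these lists passed was not tested. At 10 or more reads the long list passed in either library (1.52) but not with the nearest 50 genes (1.28), where other list members were among the possible draws. With minima of 2 reads, chromosomes 1 to 19 and X, or the nearest 50 genes, no list passed. The matched ratios above 1 held at a minimum of 1 read. At 2 or more nonredundant reads in either library, core essential complexes (0.763) and olfactory, vomeronasal and taste receptors (0.796) were below 1 with matching. No paired analysis was possible because each table pools its 2 samples, and leaving out a sample could not be run for the same reason. Alternatives on site merging, shared positions, categories, random positions, start site windows, nearest genes, site weights and orientation were not run, as the tables give no positions. With a median of 1 read per gene, depth limits any statement that a gene was not hit.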

Other observations

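All tests in this part were chosen after the results were seen. Genes with few reads were also found in both libraries more often than length-matched genes. Of the genes with 1 read in library 1, 678 of 2241 were listed in library 2, which is 1.21 times the length-matched expectation, and the ratio was 1.21, 1.16 and 1.22 for genes with 2 to 9, 10 to 99 and 100 or more reads. In library 2 it was 1.19, 1.20 and 1.21 below 100 reads and 1.41 at 100 or more, where 60 of 78 genes were listed in library 1 (permutation test, adjusted p = 0.000267). The difference between read classes was not tested.

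The excess of shared genes was weighed against gene length, overlapping genes counted separately, and carry-over of reads between libraries. As the whole cause, length is argued against by the 1732 shared genes, above the 1393 to 1484 of 95% of length-matched draws, overlapping genes by 1757 shared loci (1449 to 1538), and carry-over from genes of 100 or more reads by the 1603 shared without them (1284 to 1373). Some carry-over may still be present. Among 78 genes with 100 or more reads in library 2, reads in library 1 rose with those in library 2 once length rank was taken out (rho across genes 0.395, one-sided permutation p = 0.0004, and 0.296 with length left in). Among 125 genes with 100 or more reads in library 1, reads in library 2 rose likewise (rho 0.258, one-sided permutation p = 0.0021). With length left in, this second rho was 0.0886, so it depends on how length is handled. At most 1.43% of genes with 1 read had 100 or more in the other library. With only 78 and 125 genes of 100 or more reads, this share had to be small. It shows that such genes can account for few listings of 1 read, but not whether carry-over occurred. The 5 genes with most reads in library 2 all had reads in library 1, numbers reached by 2 (Stx1a), 5 (Slc8b1), 6 (Ski), 12 (Cpeb1) and 37 (Nrxn3) of their 200 neighbours in length, and of the 5 in library 1, Myo6, D6Wsu163e and Map7 had reads in library 2 reached by 3, 9 and 16 neighbours, while Ralgapa1 and Clnk were not listed there. A preference of the transposon or of gene trap selection for the same genes, which would give a positive rho too, a common parent pool and carry-over from genes with fewer reads stay open, and no biological explanation was tested. The Y-linked genes Kdm5d (2 and 2 reads) and Rbmy (1 and 1) were also in both libraries, while the other listed Y-linked genes were in a single one. A shared listing at few reads therefore need not mean that both libraries hit the gene.

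X-linked genes numbered 150 in library 1 against 175.9 expected from length, below the central 95% of draws (157 to 195; permutation p = 0.0098, adjusted p = 0.118), and 116 in library 2 against 131.7 (114 to 150; permutation p = 0.0906, adjusted p = 0.514). Neither passed adjustment. If the X were at 1 copy and chromosomes 1 to 19 at 2 copies, 104.4 genes (95% of draws 88 to 121) and 75.3 (61 to 90) would be expected. Both libraries lay above these ranges. This would argue against such a copy number only if listing depended on length and copy number alone. Y-linked genes, described next, were also listed within the range expected from length. Listing at 1 read thus need not follow copy number, and the comparison cannot decide. At 2 or more reads, 78 X-linked genes were listed in library 1 against 82.8 expected from length, and 47 in library 2 against 54.5. At 10 or more reads, library 1 was above the expectation (25 against 20.7) and library 2 below it (8 against 12.5). All of these lay within the central 95% of draws. Whether a deficit on the X exists stays open.

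Y-linked genes numbered 3 in library 1 against 5.52 expected from length (95% of draws 2 to 10) and 7 in library 2 against 3.80 (1 to 7). Neither passed (permutation test, adjusted p = 0.525 and 0.514). All had at most 2 reads, among them Kdm5d with 2 and 2, Ddx3y with 0 and 2 and Uty with 0 and 1. A single chromosome set that holds an X holds no Y, and 150 and 116 X-linked genes were listed. Listing at 1 or 2 reads is therefore weak evidence that a gene was hit. The source of the Y-linked reads was not tested.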
